A study of Pseudomonas putida with 4 samples.

How the data were processed

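Total RNA was measured in 4 strains of the soil bacterium *Pseudomonas putida* KT2440: the wild type, a strain with *crc* deleted, a strain with *hfq* deleted and a strain with both deleted. All were grown in M9 minimal medium on succinate and harvested at a turbidity of 0.6, and each genotype is represented by 1 library. Per the labels' protocols, ribosomal RNA was removed with Ribo-Zero, and directional TruSeq libraries were sequenced as single-end reads of 150 nt. The submitters' processing notes name FastQC, Bowtie2, HTSeq and edgeR. Their versions, their parameters, the genome build and the annotation are not given in the sources used here.

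The deposited table gives 1 signal value per library for 5350 locus tags. The authors' values are not whole numbers, but each column is made of whole multiples of 1 step, so that gene read counts could be recovered by dividing by that step. All 100.0% of the values came out whole within 0.006 of the deposited unit, and in data simulated with known reads 100.0% of the reads were recovered exactly. One read was worth 1.05 in the wild-type column, 0.966 in the *crc* column, 1.41 in the *hfq* column and 1.08 in the column of both deletions. The recovered reads came to 1202214 for the wild type, 1817347 for the *crc* deletion, 1659478 for the *hfq* deletion and 1831808 for the double deletion. These depths limit the precision: a count of 0 allows up to 2.50 CPM (reads relative to all recovered reads of the library) in the wild type and 1.64 to 1.81 in the mutants, taking 3 reads as the limit. Intervals given with fold differences are 95% counting intervals of the reads, which cover counting error only and not the variation between cultures. Reads are not independent molecules, because the libraries were amplified without molecular identifiers.

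The deposited columns keep different totals and medians, so that ratios between them carry a shift common to all genes. The median log2 ratio over the 4204 measured genes was 1.18 for the *hfq* deletion against the wild type, 0.36 for the *crc* deletion and 0.63 for the double deletion. The comparisons had been fixed on the values as deposited before the data were examined, and the counts made that way are reported. Values of named genes and of gene lists are reported relative to this shift. They come from the recovered reads divided by median-of-ratios size factors and put on a CPM scale with 1 constant for all 4 libraries, called rescaled values here.

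A gene counted as measured when its mean over the 4 libraries was at least 10 CPM on the deposited values divided by 1 constant common to the 4 libraries, which left 4204 genes and put aside 1146. Log2 ratios were taken after adding a pseudocount of 1 CPM, which understates the change of genes at low levels. With 1 library per genotype, a comparison of 2 libraries has no replicate check and no p-value: a gene was counted as higher or lower by size alone, at 2-fold or more. The strains also form a 2 by 2 design. The effect of each deletion across both backgrounds was therefore tested over the 4 libraries with limma (version 3.58.1, R 4.3.3), with a robust empirical Bayes trend and the other deletion as an additive term. This fit leaves 1 residual degree of freedom, any interaction between the deletions counts as error, and the p-values measure the spread between genotypes and not between replicate cultures. P-values were adjusted by the Benjamini-Hochberg method at 0.05. On data simulated for the *hfq* effect over 4204 genes, 200 of them changed, with a coefficient of variation of 20%, the test found 7.5% of 2-fold, 97% of 4-fold and 99.5% of 8-fold changes. At 10% it found 80.5% of 2-fold changes. The simulated effects were the same in both backgrounds, and the simulated reads were scaled by median-of-ratios. These rates therefore do not cover genes whose effect differs between backgrounds, or the test on the values as deposited. In the simulated comparison of the *hfq*-deleted and wild-type libraries, the 2-fold rule called 46 to 52 unchanged genes at 10% and 166 to 188 at 20%.

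Alternatives fixed before the data were examined were median-of-ratios, TMM and equal-total scaling, pseudocounts of 0.1 and 5, no filter on level, a minimum level of 50, limma without trend or robust prior, and DESeq2 (1.42.0). DESeq2 was to be used only on counts, and was run on the recovered reads. Chosen after the data were seen were edgeR's quasi-likelihood test (4.0.16) on the recovered reads, cyclic loess on the rescaled values, the fits without the tags PP_3849 to PP_3920, and median-of-ratios scaling for the correlations between backgrounds. The use of the rescaled values as the main scale for named genes, gene lists, overlaps and runs was also chosen then. The additive fits with other pseudocounts, other level filters, no trend or robust prior, or without PP_3849 to PP_3920 all kept the values as deposited. Tallies of fits passed therefore count that scale repeatedly. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.

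The table pairs no names with its locus tags, and 0 of the 5350 tags matched the RefSeq table at hand, which describes another strain of *P. putida*. The names printed here are those written beside a tag when the gene lists were fixed before the data were examined. They come from knowledge of the strain's locus tags and were not checked against an annotation. Only the 11 lists that had been fixed at least in part by tag could be used, with 100 tags, all of them in the table. The lists overlap: the iron-using and redox enzymes include PP_0944 and PP_0946 of the PP_0943 group. They also include PP_4190 to PP_4193 of the tricarboxylic acid cycle list. Lists defined by symbol or product alone, such as siderophore receptors, ECF sigma factors, flagella, amino acid use, ribosomal proteins and small RNAs, were not analysed here. Genes to be named were fixed by rule: the 10 highest and 10 lowest ratios in each of the 3 comparisons with the wild type, the 5 highest and 5 lowest among genes at least 2-fold different the same way in both backgrounds, and up to 4 members of a list. Of the genes this rule selected, those with no name in the lists are summarised, with at most a few tags printed. A list's median was set against the medians of 10000 random lists of the same size matched on mean level, as a description of these libraries. The random genes were drawn singly, while many of the lists hold neighbouring tags that can vary together. An extreme percentile is therefore no measure of how rarely such a list would arise without an effect of the deletion.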

Results

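Gene expression was measured by RNA sequencing in *P. putida* KT2440 and in strains lacking Crc, Hfq or both. Hfq is an RNA-binding protein that acts on the translation and stability of many messenger RNAs, and Crc works with it in the repression of catabolic genes when a preferred carbon source such as succinate is present. The series asked how both regulators influence iron homeostasis. Each genotype had 1 library, with 1202214 to 1831808 recovered reads over 5350 genes. The 20 most abundant genes took 19.5% to 20.8% of the reads of a library.

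The deleted genes were examined first. *hfq* (PP_4894) had 599 reads in the wild type, 1198 in the *crc* deletion, 1 in the *hfq* deletion and 0 in the double deletion. The library of the *hfq* deletion was 1114-fold lower than the wild type, with a counting interval of 199 to 44090. The double deletion was at least 304-fold lower when 3 reads are taken as the limit, and its counting interval begins at 246-fold. *crc* (PP_5292) had 493 reads in the wild type and 697 in the *hfq* deletion, against 33 in the *crc* deletion and 41 in the double deletion. Its level in the *crc* deletion was 20.1-fold lower than in the wild type (14.1 to 29.6). In the double deletion it was 18.3-fold lower (13.3 to 25.8). The differences went the way the genotype labels call for, but the source of the *crc* reads left in both *crc*-deleted libraries was not examined. *pyrE* (PP_5291), which has the tag next to *crc* and encodes an enzyme of pyrimidine synthesis, was 5.92-fold higher in the *crc* deletion than in the wild type (5.002 to 7.05), with 1221 against 153 reads, and had 1762 reads in the double deletion. Among the other listed neighbours and partners of *hfq* and *crc*, *cbrB* (PP_4696), a response regulator upstream of this pathway, had log2 ratios of -0.295 in the *hfq* deletion, -0.38 in the *crc* deletion and -0.56 in the double deletion. As deposited they were 1.02, -0.07 and 0.09, so that its direction depended on scaling in the *hfq* and double deletions. Without *hfq* and *crc*, the median of the 8 remaining tags of this list was -0.11, 0.33 and 0.17 in the 3 mutants, and the first of these was 1.202 as deposited, 0.32 with equal totals and 0.26 after cyclic loess.

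The comparison of the *hfq* deletion with the wild type asks what changes when Hfq is absent. Genes for pyoverdine, the siderophore with which this bacterium takes up iron, had lower values: 16 of the 20 measured tags of that list were at least 2-fold lower and 2 were at least 2-fold higher. The list median was -1.71 on the log2 scale, below all 10000 random lists of matched level, which were drawn gene by gene. As deposited it was -0.43, with 7 tags at least 2-fold lower and 2 higher. The lowest member was PP_4218 at 11.2-fold lower (7.50 to 17.2), with 29 against 174 reads. The exceptions were PP_4208 and PP_4244, with log2 ratios of 1.53 and 1.84. PP_4244 reached the minimum level through the libraries with *hfq* deleted, so the filter favoured its rise. Its rescaled level was 18.04 CPM in the *hfq* deletion and 20.38 in the double deletion. It was 4.3 in the wild type and 1.28 in the *crc* deletion. All 8 tags of the iron-sulfur cluster assembly list, PP_0841 to PP_0848, had higher values, 2 of them by 2-fold or more (8 as deposited), with a median of 0.84 that lay above all matched random lists. The tag PP_0841 had a log2 ratio of 1.54. In the group PP_0943 to PP_0946 both measured tags were at least 2-fold higher. They were *sodA* (PP_0946), a superoxide dismutase that uses manganese, and *fumC* (PP_0944), a fumarase that needs no iron-sulfur cluster. *sodA* had 40 against 1 read, a ratio of 21.5 with a counting interval of 3.64 to 870, and *fumC* had a log2 ratio of 1.25. The tags PP_0943 and PP_0945 lay under the minimum level. *sodA* reached it through the libraries with *hfq* deleted: its rescaled level was 18.5 CPM in the *hfq* deletion, 0.86 in the wild type and 4.47 in the *crc* deletion. The filter itself thus favoured a rise of *sodA*. The fumarase gene *fumA* (PP_0897) had a log2 ratio of -1.38, or -0.06 as deposited, and the catalase gene *katA* (PP_0481) one of -1.17, or 0.14 as deposited. Over the 15 iron-using and redox enzymes, a list that also holds *sodA* and *fumC*, the median was -0.51. The 2 members at least 2-fold higher were *sodA* and *fumC* again, and the 2 at least 2-fold lower were *fumA* and *katA*. As deposited the median was 0.80, with 6 higher and 0 lower.

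Genes of central metabolism and stress were examined in the same comparison. The 10 tags of the tricarboxylic acid cycle list had a median of -0.61, or 0.71 as deposited, and 0 of them reached 2-fold. Random lists of the same level had a median of -0.61 as well. The 5 terminal oxidase tags had a median of -0.76, or 0.56 as deposited, which lay at percentile 20.9 of the matched lists. The 14 measured tags for glucose use had a median of 0.05, with 0 at least 2-fold higher and 1 lower. That median was 1.34 as deposited, with 9 tags higher and 0 lower, and 0.47 with equal totals. The 6 polyhydroxyalkanoate tags had a median of -0.08, or 1.21 as deposited and 0.34 with equal totals. Of the 10 heat shock genes, 9 were above 0, with a median of 0.45 that exceeded all matched lists and 0 members at 2-fold (10 as deposited). *rpoS* (PP_1623), the sigma factor of stationary phase, had a log2 ratio of -0.30, or 1.02 as deposited, 0.13 with equal totals and 0.11 after cyclic loess.

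The highest ratios lay at neighbouring tags with no name in the lists. PP_0552 to PP_0555 were 28.0- to 39.7-fold higher in the *hfq* deletion than in the wild type. Of the 10 lowest genes, 7 were tags between PP_3849 and PP_3920. Over these 72 tags the wild type had 1264 reads and the *crc* deletion 1742, while both libraries of *hfq*-deleted strains had 0, where 2352 reads were expected in the *hfq* deletion at the wild-type level. Every effect of *hfq* given here is therefore measured between strains that also differ in the reads of this segment. On the values as deposited, 2695 genes were at least 2-fold higher and 35 lower. On the rescaled values the split was 249 higher and 222 lower. The ratio also varied with level: on the rescaled values its median was 0.38 in the lowest decile of expression and -0.55 in the highest. In the *crc* deletion these medians were -0.37 and 0.24, and in the double deletion -0.05 and -0.01.

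**Figure D1:**
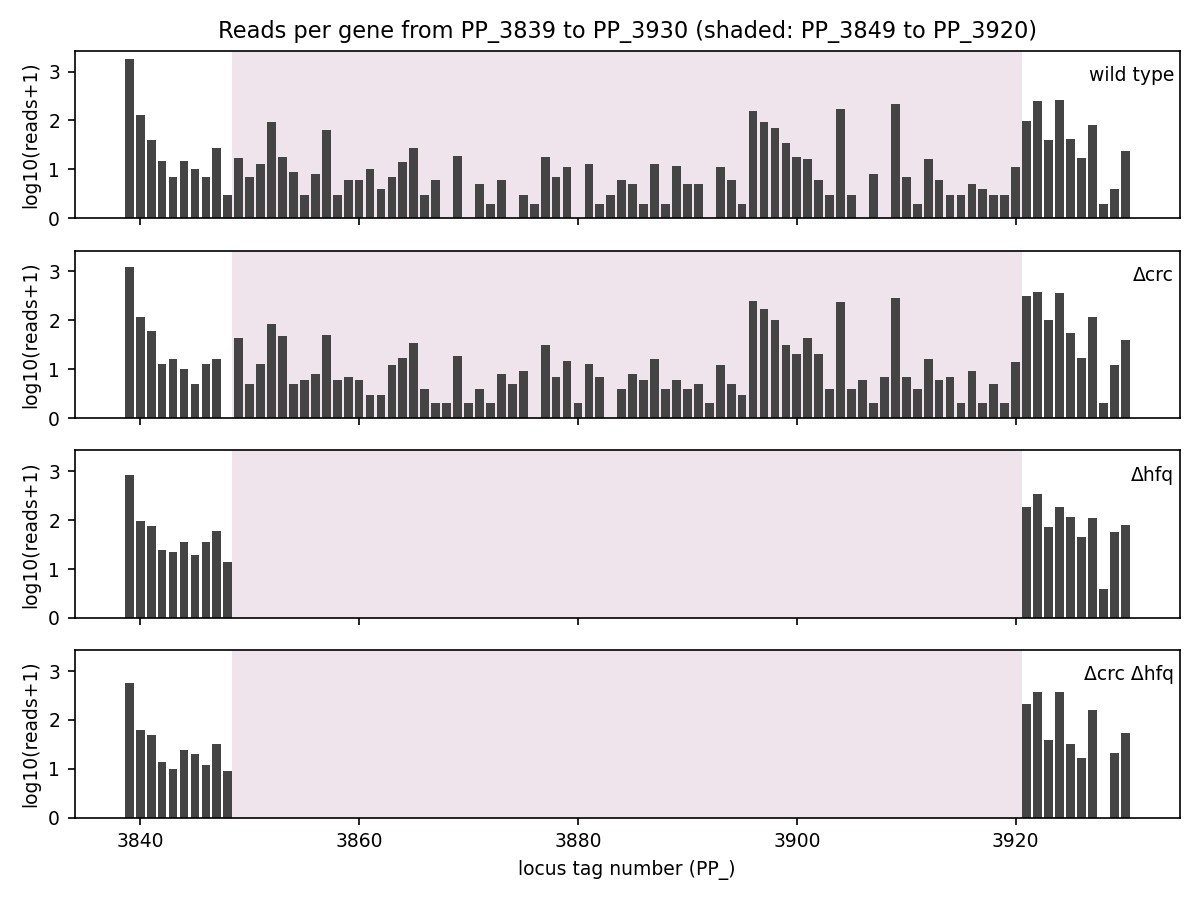
Recovered reads per gene, as log10(reads + 1), for the locus tags PP_3839 to PP_3930 in each of the 4 libraries, with PP_3849 to PP_3920 shaded. The 72 shaded tags held 1264 reads in the wild type and 1742 in the *crc* deletion, and 0 in the *hfq* deletion and the double deletion.

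The comparison of the *crc* deletion with the wild type asks the same of Crc. The pyoverdine list was again the lowest: 18 of the 20 measured tags were at least 2-fold lower, with a median of -2.24, below all matched random lists. As deposited, 17 were lower and 1 higher. The 18 include PP_4244 on 2 against 5 reads, 3.37-fold lower with a counting interval of 0.55 to 35.4 that includes no change. PP_4220 was 14.5-fold lower (12.4 to 16.9), with 186 against 1997 reads, and PP_4219 was 12.1-fold lower (10.3 to 14.2). Of the 10 lowest genes, 7 were on this list. PP_4217 had a log2 ratio of -0.23, or 0.08 as deposited. The 8 iron-sulfur assembly tags were all above 0, with a median of 0.56 at percentile 96.1 and 1 member at 2-fold (2 as deposited). *katA* had a log2 ratio of -1.14, or -0.83 as deposited, *katG* (PP_3668), a catalase-peroxidase, one of -1.09, or -0.78 as deposited, and *sodA* one of 1.56 on 7 against 1 read, a ratio of 5.195 with a counting interval of 0.667 to 234 that includes no change. The 15 iron-using and redox enzymes had a median of -0.21, or 0.10 as deposited, and in the PP_0943 group *sodA* was the 1 of 2 measured tags at least 2-fold higher.

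The remaining lists were examined in the same way. The tricarboxylic acid cycle list had a median of 0.13, or -0.04 with equal totals and -0.14 after cyclic loess. The terminal oxidase list had one of -0.15, or 0.16 as deposited. The glucose list had a median of 0.32 at percentile 97.46, with PP_1009 at 1.33. The polyhydroxyalkanoate list, genes of a carbon storage polymer, had a median of -0.58 at percentile 1.89, or -0.27 as deposited, with PP_5003 at -1.12 (-0.81 as deposited). The heat shock list had a median of 0.64 at percentile 99.95, with *grpE* (PP_4728) at 1.26 and *clpB* (PP_0625) at -0.81. *rpoS* had a log2 ratio of -0.63. Apart from *pyrE*, the highest gene with ample reads was PP_4007, 4.92-fold higher (3.81 to 6.43). As deposited, 480 genes were at least 2-fold higher and 136 lower, and on the rescaled values 177 were higher and 282 lower.

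In the double deletion, compared with the wild type, the pyoverdine list lay below 0 and the iron-sulfur assembly list above 0 once more. Of the 20 measured pyoverdine tags, 18 were at least 2-fold lower and 2 at least 2-fold higher, with a median of -2.72. As deposited, 14 were lower and 2 higher. PP_4220 had a log2 ratio of -4.33. All 8 iron-sulfur assembly tags were at least 2-fold higher, with a median of 1.64, above all matched lists, and log2 ratios from 1.35 to 2.36. *sodA* had a log2 ratio of 2.51 on 17 against 1 read, and *ahpC* (PP_2439), a peroxidase subunit, one of 1.51. *katA* had one of -1.72, and *fumA* one of -1.199, or -0.55 as deposited. The 15 iron-using and redox enzymes had a median of -0.51 at percentile 0.27, or 0.14 as deposited.

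The remaining lists were also compared with the wild type. The heat shock list had a median of -0.99 at percentile 0.04, or -0.34 as deposited, with 5 of 10 genes at least 2-fold lower (1 as deposited), *clpB* at -2.95 and *hslU* (PP_5001) at -1.48 (-0.84 as deposited). The polyhydroxyalkanoate list had a median of -1.21 at percentile 0.06, with 3 of 6 tags at least 2-fold lower, or -0.58 with 1 of 6 as deposited. The tricarboxylic acid cycle list had a median of -0.61 at percentile 0.07, or 0.04 as deposited, with 0 tags at 2-fold, and the terminal oxidase list one of -0.43, or 0.22 as deposited. The glucose list had a median of 0.09, with PP_1022 at -1.90. *rpoS* had a log2 ratio of -0.82. PP_0552 to PP_0555 were 50.1- to 64.7-fold higher than in the wild type. As deposited, 1226 genes were at least 2-fold higher and 148 lower, and on the rescaled values 353 were higher and 394 lower.

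**Figure D2:**
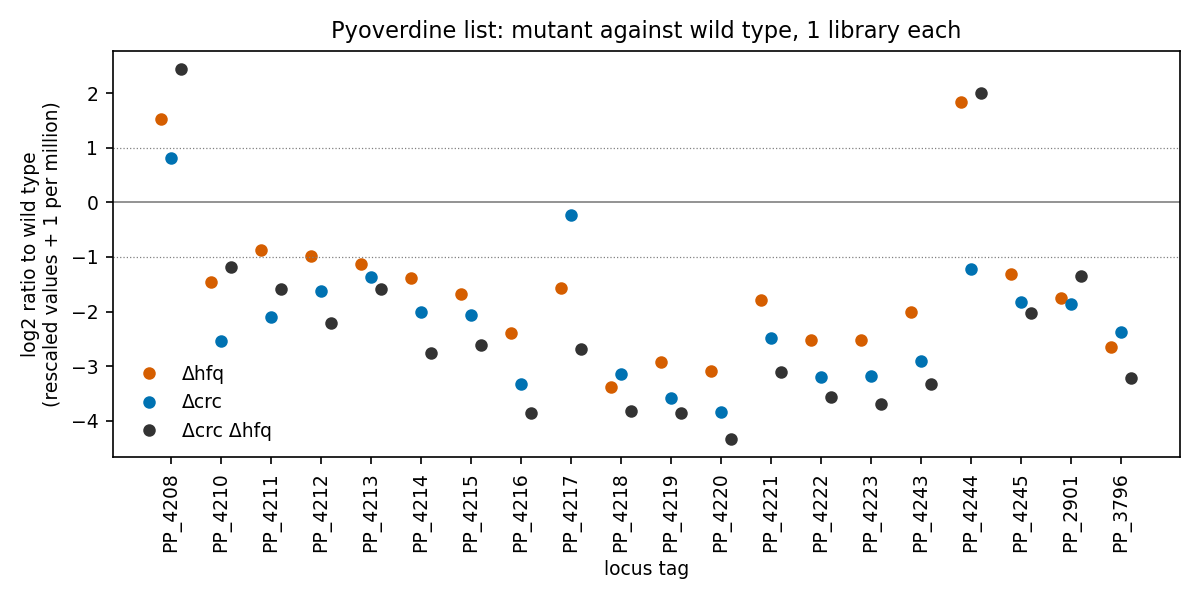
Log2 ratio of each mutant to the wild type (rescaled values + 1 CPM) for the 20 measured tags of the pyoverdine list, 1 library per genotype. Dotted lines mark 2-fold. Of the 20 tags, 16 were at least 2-fold lower in the *hfq* deletion, 18 in the *crc* deletion and 18 in the double deletion, and the medians stayed below 0 on the values as deposited (-0.43, -1.91 and -2.08).

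**Figure D3:**
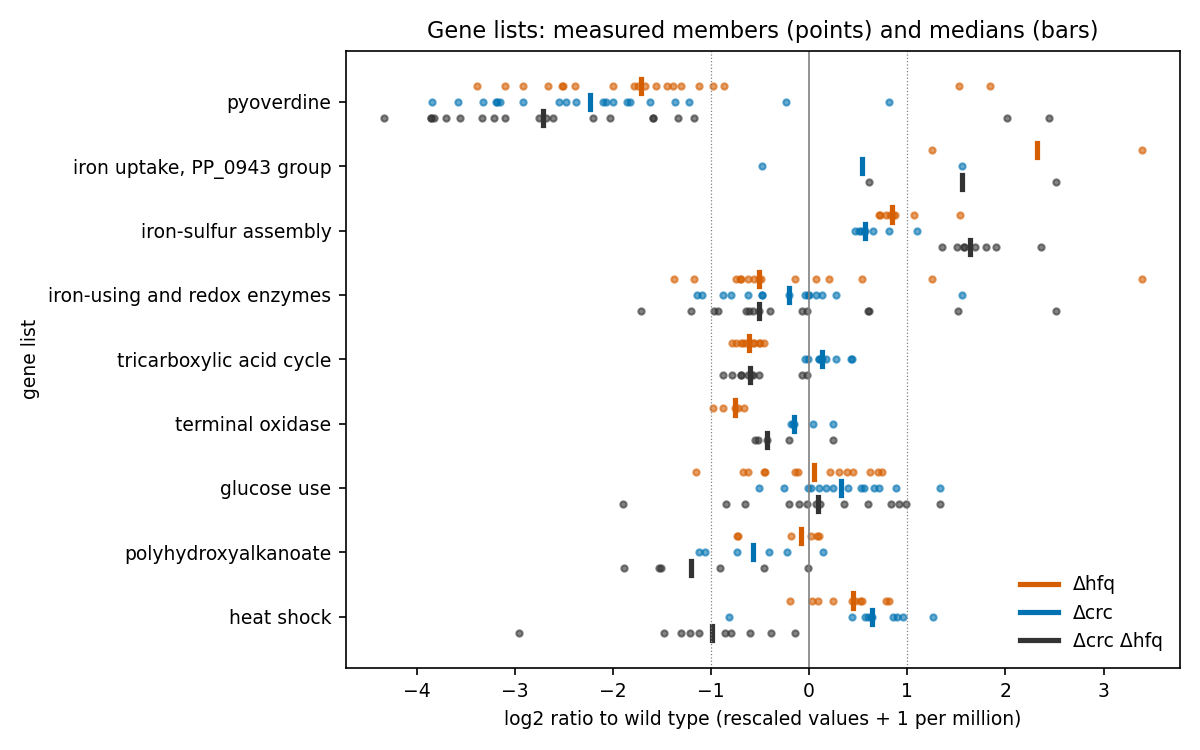
Log2 ratio to the wild type (rescaled values + 1 CPM) for the measured members of 9 gene lists, with points for genes and bars for list medians in the 3 mutants. The iron-sulfur assembly medians were 0.84, 0.56 and 1.64 in the *hfq*, *crc* and double deletions. The heat shock medians were 0.45, 0.64 and -0.99. As deposited, the medians of the tricarboxylic acid cycle list in the *hfq* and double deletions and those of the terminal oxidase and iron-using and redox enzyme lists in all 3 mutants lay above 0, and so did that of the polyhydroxyalkanoate list in the *hfq* deletion.

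Genes that differed the same way in several mutants were counted next, against simulations, since the wild-type library stands in every comparison. On the rescaled values 65 genes were at least 2-fold lower in all 3, of which 15 were on the pyoverdine list, and 21 were higher in all 3. Unchanged mutants simulated against the common wild-type library at a coefficient of variation of 20% gave 3.2, 0 and 21.7, and with counting error alone 0.3, 0 and 5.3. These simulations drew each gene independently, so they could not produce genes that vary together in the wild-type culture. The simulated 0 for the pyoverdine list therefore cannot exclude that library as the source of the 15. At 20% the common library alone would thus give as many genes higher in all 3 as were found, and the variation between cultures was not measured. The *hfq* and *crc* deletions shared 28 higher and 67 lower genes (364 and 19 as deposited), where independent lists would share 10.5 and 14.9. Across genes the log2 ratios of these comparisons correlated with r = 0.225, genes not being independent replicates. The simulated mutants shared 37.3 higher and 12.2 lower genes, with r = 0.541 and a covariance of 0.135 against the observed 0.112, so that only the shared lower genes exceeded this simulation. For the *hfq* and double deletions the shared genes were 98 higher and 133 lower (940 and 34 as deposited, 20.9 and 20.8 for independent lists, 38.7 and 11 simulated). Their r was 0.584, against 0.549 simulated, and their covariance 0.419, against 0.136. For the *crc* and double deletions they were 103 higher and 155 lower (406 and 61 as deposited, 14.9 and 26.4 for independent lists, 38.2 and 12.8 simulated), with r = 0.598 against 0.536 and a covariance of 0.369 against 0.136. The single wild-type library cannot be split, so part of each excess may come from it.

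The double deletion was next set against each deletion alone, which gives the effect of the second deletion where the first is already present. Against the *crc* deletion, the pyoverdine list had a further median of -0.46 at percentile 0.09, or -0.125 as deposited, with 1 of 20 tags at least 2-fold lower and 3 at least 2-fold higher on both scales. The iron-sulfur assembly list had a median of 1.06, with 5 of 8 tags at 2-fold (8 as deposited), and the heat shock list one of -1.80, with 9 of 10 genes at least 2-fold lower on both scales. The tricarboxylic acid cycle list had a median of -0.79, or -0.45 as deposited, with 2 of 10 tags at least 2-fold lower (0 as deposited). Medians that changed sign as deposited were those of the iron-using and redox (-0.21 to 0.13), terminal oxidase (-0.28 to 0.06), glucose (-0.25 to 0.08) and *hfq* and *crc* neighbour lists (-0.15 to 0.18), and the ratio of *rpoS* (-0.19 to 0.14). After cyclic loess the first was 0.025, that of the neighbours 0.066 and that of *rpoS* 0.034, and with equal totals that of the neighbours was 0.009.

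Against the *hfq* deletion, 9 of 20 pyoverdine tags were at least 2-fold lower (16 as deposited) and 0 at least 2-fold higher, with a median of -0.94 at percentile 0, or -1.595 as deposited. The heat shock median was -1.36, or -2.04 as deposited, with 6 of 10 genes at least 2-fold lower (10 as deposited). The iron-sulfur assembly median depended on scaling: it was 0.77 at percentile 90.8, with 1 of 8 tags at 2-fold, and 0.44 after cyclic loess, 0.34 with equal totals and 0.10 as deposited, with 0 tags at 2-fold. Medians that changed sign were those of the terminal oxidase list (0.45, or -0.22 as deposited and -0.16 after cyclic loess), the glucose list (0.15, or -0.51 as deposited and -0.27 with equal totals) and the *hfq* and *crc* neighbours (0.22, or -0.45 as deposited, -0.21 with equal totals and -0.28 after cyclic loess). The counts as deposited were 441 higher and 91 lower against the *crc* deletion, and 74 higher and 1215 lower against the *hfq* deletion. On the rescaled values they were 216 and 179, and 422 and 323.

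**Figure D4:**
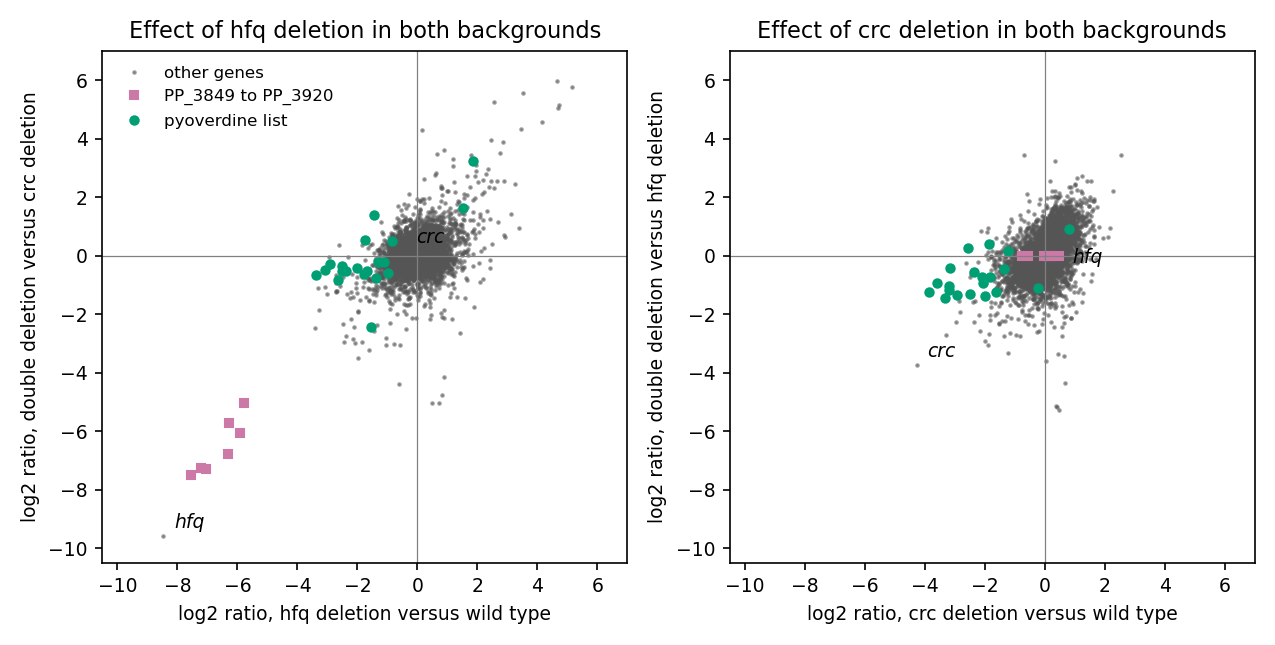
Log2 ratios (rescaled values + 1 CPM) of the measured genes for *hfq* deletion (left) and *crc* deletion (right), in the wild-type background (horizontal axis) and in the background lacking the other gene (vertical axis), with no library in common between the axes. Across genes r was 0.53 for *hfq* and 0.494 for *crc*, and 0.464 for *hfq* without the tags PP_3849 to PP_3920.

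The effect of each deletion was compared between backgrounds, using pairs of ratios with no library in common. For *hfq*, Pearson's r across the 4204 genes was 0.531 as deposited and 0.53 on the rescaled values, with Spearman's rho 0.305. On the rescaled values 85 genes were at least 2-fold higher and 65 at least 2-fold lower in both backgrounds, where independent lists would share 12.8 and 9.5, and 11 went opposite ways. Of the 65, 7 lay between PP_3849 and PP_3920. For *crc*, r was 0.497 as deposited and 0.494 rescaled, with rho 0.524, and 77 genes were higher and 82 lower in both, against 17.8 and 21.7 for independent lists, with 8 opposite. For 598 genes the effect differed by 2-fold or more between backgrounds, a difference that 4 libraries do not allow to be tested.

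The additive test over the 4 libraries asked which genes followed each deletion in both backgrounds. For *hfq*, limma on the values as deposited called 55 genes that rose and 9 that fell, and on the rescaled values 85 that rose and 89 that fell, with 53 genes called both times. Besides *hfq* itself, at a log2 effect of -9.02 ± 0.33 (SE) on the rescaled values, PP_0553 rose by 5.45 ± 0.29. Both passed in all 13 fits that were run with limma, edgeR and DESeq2, and limma with TMM scaling gave both their highest adjusted p, 0.0018. For *crc*, the same test called 1 gene that rose and 6 that fell as deposited, and 210 and 118 on the rescaled values, with 6 called both times. With TMM scaling limma called 0 that rose and 1 that fell. That gene was *crc* itself, which fell by 4.00 ± 0.27 on the rescaled values and passed in all 13 fits, with an adjusted p of 0.033 with TMM. *pyrE* rose by 2.997 ± 0.28, and PP_0588 and PP_5393 fell, in 12 of the 13 fits. All 3 missed the threshold with TMM scaling, where limma's adjusted p was 0.061 for each, against 0.0090 for each as deposited.

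Within the lists, the limma test with TMM scaling called 0 pyoverdine and 0 iron-sulfur assembly tags for either deletion. The edgeR test, which also scaled by TMM, called 4 pyoverdine tags for *hfq* and 11 for *crc*, and 5 and 0 iron-sulfur assembly tags. The calls that follow therefore depend on the scaling and on the test together. For *hfq*, the test on rescaled values called 4 of 20 pyoverdine tags, 10 when adjusted over the list alone (8 that fell and 2 that rose), and 1 as deposited. PP_4217 fell by 2.005 ± 0.27, with limma's adjusted p at 0.00045 rescaled and 0.56 as deposited, and passed in 5 of 13 fits. PP_4208 and PP_4244 were the tags that rose, in 5 of 12 and 10 of 11 fits that gave an adjusted p. The filter on level favoured the rise of PP_4244. For *crc* the test called 8 pyoverdine tags, all of which fell, 14 when adjusted over the list alone (13 fell), and 1 as deposited. PP_4221 fell by 1.90 ± 0.30, with limma's adjusted p at 0.0052 rescaled and 0.25 as deposited, and passed in 5 of 13 fits. PP_4220 had a log2 ratio of -3.84 for *crc* deletion in the wild-type background and -1.24 in the background lacking *hfq*. Its adjusted p in limma was 0.012 as deposited and 0.30 rescaled. It passed in 7 of 13 fits, all 7 on the values as deposited, and in no fit on another scale. The iron-sulfur assembly list had 4 of 8 tags that rose with *hfq* deleted on the rescaled values, 8 when adjusted over the list alone, and 2 as deposited. PP_0841 rose by 1.40 ± 0.25, with limma's adjusted p at 0.0033 rescaled, 0.035 as deposited and 0.066 with TMM, the only one of 13 fits in which it missed the threshold. With *crc* deleted 1 of the 8 rose on the rescaled values, 8 when adjusted over the list alone, and 0 in each of the other 12 fits.

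For *hfq* deletion, *sodA* passed in 4 of the 11 fits that gave an adjusted p, all 4 of them limma fits to the values as deposited. The planned limma fit as deposited was among them (0.031), and limma on the rescaled values was not (0.093). The adjusted p ranged from 0.00018 to 0.30 over the 11 fits. In limma on the rescaled values 0 of the 2 tags of the PP_0943 group passed, while 2 had an unadjusted p below 0.05 and 2 passed adjusted over the list alone. In edgeR 1 passed, and DESeq2 gave an adjusted p for *fumC* only, which did not pass. For *crc* deletion 0 of these 2 passed in limma or edgeR, limma on the rescaled values gave 0 at an unadjusted p below 0.05, and DESeq2 gave no adjusted p for either. *fumA* was the 1 of 15 iron-using and redox enzymes called for *hfq* on the rescaled values, with an effect of -1.18 ± 0.31, and 5 passed adjusted over the list alone. Its adjusted p was 0.042 there, 0.61 as deposited, 0.16 with TMM and 0.062 in edgeR, and it passed in 2 of 13 fits. *katG* was the 1 called for *crc*, with an effect of -1.04 ± 0.28, and was also the 1 called over the list alone. Its adjusted p in limma was 0.035 rescaled and 0.9996 as deposited, and it passed in 3 of 13 fits. On the rescaled values 2 of 14 glucose tags were called lower with *hfq* deleted, also over the list alone, with 0 called as deposited, with TMM or in DESeq2. The polyhydroxyalkanoate list had 1 of 6 tags called lower with *crc* deleted, PP_5003, also over the list alone. It passed in 4 of 13 fits, with adjusted p from 0.00078 to 1.0. The tricarboxylic acid cycle and terminal oxidase lists had 0 genes called in the 13 fits for either deletion, and 0 adjusted over the list alone. The heat shock list had 0 for *hfq*, and for *crc* 1 gene in DESeq2 and 0 in the other 12 fits, with 0 adjusted over the list alone. At an unadjusted p below 0.05 on the rescaled values, limma gave 4 tricarboxylic acid cycle tags for *hfq* and 0 for *crc*, 0 and 1 terminal oxidase tags, and 1 and 1 heat shock genes. *rpoS*, the only member of its list that could be used, was called for *hfq* in 0 of 13 fits (0 at an unadjusted p below 0.05 in limma on the rescaled values). For *crc* it was called in 1, after cyclic loess, and when adjusted over the list alone.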

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

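The tests of the segment PP_3849 to PP_3920, of the trend with expression level and of the deposited factor were chosen after those results were seen, and so was the criterion for lists that move opposite ways, which asks for at least 75% of the members to lie on opposite sides of 0.

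The heat shock list moved one way in one background and the other way in the other. With *hfq* deleted, its median log2 ratio was 0.448 against the wild type and -1.799 in the background lacking *crc*, and with *crc* deleted it was 0.638 against the wild type and -1.363 in the background lacking *hfq*. The signs were the same as deposited (1.768, -1.465, 0.948 and -2.036). For each gene the difference between backgrounds is the same quantity for both deletions, so both pairs of medians show 1 observation. The 11 lists were screened for both deletions, and no other list met the criterion. The difference was not tested, since 4 libraries leave no degree of freedom for an interaction, and all 4 values rest on 1 library per genotype.

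Both libraries of *hfq*-deleted strains lacked reads over 72 neighbouring tags, PP_3849 to PP_3920. At the wild-type level 2351.8 reads were expected in the *hfq* deletion and 0 were found, which argues against too little depth. The tags without reads formed 1 unbroken run of 72 in both libraries, and the longest such run elsewhere was 3 tags in any library, which is what a segment missing from the chromosome of both strains would give. With 3 reads taken as the limit, the segment was at least 783.9-fold lower than the wild type in the *hfq* deletion. In the double deletion it was at least 640.6-fold lower. These bounds leave out the counting error of the wild-type reads. A loss of transcription without Hfq cannot be told apart from a missing segment, because no DNA was measured and every *hfq*-deleted strain lacks the reads. A candidate explanation is a loss of the segment in the lineage of the *hfq* deletion, and under it differences ascribed to *hfq* could in part belong to the segment.

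In the *hfq* deletion against the wild type, genes at low levels tended to be higher and genes at high levels lower, with medians of 0.381 in the lowest decile and -0.554 in the highest. The double deletion against the *crc* deletion gave 0.285 and -0.253, but the double deletion against the wild type -0.048 and -0.008, and the *crc* deletion against the wild type the opposite, -0.374 and 0.242. The tests that follow concern the *hfq* deletion against the wild type. A constant amount of background reads, fitted to the lowest decile at 5.05 CPM, predicts a difference of -0.103 between the medians of deciles 10 and 6, and the observed one was -0.408 (bootstrap interval -0.465 to -0.328), which argues against it. Cyclic loess, which removes the trend, left 395 genes at 2-fold, of which 332 were among the 471 called before, so the trend alone did not make most of these calls. A direct effect of the deletion and a difference in library preparation remain open and were not tested.

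The deposited values differed between libraries by a factor common to all genes. The factor by which reads had been multiplied followed the TMM factors computed here, with a largest over smallest ratio of 1.056, as reads multiplied by a composition factor with no division by depth would give. For reads divided by effective library size that ratio would be near 1 and was 2.357, which argues against such a scale. No biological explanation was tested for this pattern.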

How the results depend on the processing

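Among these alternatives, edgeR, cyclic loess, the fits without PP_3849 to PP_3920 and rescaling of the correlations were chosen after seeing the data. So was the use of rescaled values for named genes and gene lists. The ratios of the 10 highest and 10 lowest genes of each mutant and list medians of 2-fold or more kept their sign. Other ratios did not, such as *katA* in the *hfq* deletion (-1.17, or 0.14 as deposited), and smaller list medians changed sign in each of the 5 comparisons, most often as deposited. The number of genes at least 2-fold different in the *hfq* deletion was 2730 as deposited, and 471 with median-of-ratios scaling, 466 with TMM, 687 with equal totals, 395 after cyclic loess and 1180 at a minimum level of 50. For the *crc* deletion it was 616, and 352 at that minimum. For the double deletion it was 1374, and 747, 751, 747, 751 and 747 under the same 5 settings. Against the *crc* deletion it was 532, and 349 with a pseudocount of 5, 865 without a filter and 188 at the higher minimum. Against the *hfq* deletion it was 1289, and 745 with median-of-ratios, 767 with TMM, 635 after cyclic loess and 483 at the higher minimum. The drop at a higher minimum or rise without one follows from the number of genes counted, and the scaling changes follow from the common shift of the deposited columns. The share of higher among these calls went from 98.7% as deposited to 52.9% (median-of-ratios), 60.9% (TMM) and 86.5% (equal totals) for the *hfq* deletion, from 77.9% to 38.6%, 35.8% and 19.9% for *crc*, from 89.2% to 47.3%, 46.9% and 47.1% for the double deletion, from 82.9% to 54.7%, 56.4% and 70.5% against *crc*, and from 5.7% to 56.6%, 46.9% and 16.1% against *hfq*.

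The additive test for *hfq* called 64 genes (349 at an unadjusted p below 0.05), and 174 with median-of-ratios, 97 without a filter, 39 at a minimum of 50, 147 without trend or robust prior, 179 in edgeR and 196 after cyclic loess. TMM gave 44 (26 that rose), equal totals 86 and DESeq2 96 with 489 adjusted p-values not given. Without PP_3849 to PP_3920 it called 50, of which 48 rose. For *crc* it called 7 (134 unadjusted), and 328 with median-of-ratios, 1 with TMM (*crc* itself, with *pyrE*, PP_0588 and PP_5393 no longer called), 52 with equal totals, 31 without trend or robust prior, 329 in edgeR, 78 in DESeq2 (1141 not given) and 352 after cyclic loess. The cause was not tested. Median-of-ratios and edgeR shared 161 calls for *hfq* and 275 for *crc*. The correlation of the *hfq* effect between backgrounds was 0.531, and 0.481 with a pseudocount of 5, 0.594 at a minimum of 50, 0.503 after cyclic loess and 0.456 without PP_3849 to PP_3920. That of *crc* was 0.497, and 0.52, 0.571 and 0.453 under the first 3 of these and 0.411 without a filter. The genes shared by the *hfq* and *crc* deletions were 383, and 95 with median-of-ratios, 95 with TMM, 86 with equal totals, 239 with a pseudocount of 5, 212 at a minimum of 50 and 104 after cyclic loess. Those shared by the *hfq* and double deletions were 974, and 231, 226 and 235 with the 3 scalings, 438 at the minimum of 50 and 223 after cyclic loess. Those shared by the *crc* and double deletions were 467, and 258, 261, 273, 296 and 263 under the same settings.

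Of 360 alternative values of these highest and lowest genes 21 moved beyond their counting interval, 15 of them on the values as deposited, and of 330 alternative list medians 53 moved by more than the spread between members, 25 of them as deposited. No paired analysis was possible because each genotype has 1 library. Leaving out a library gives no alternative value, since no genotype keeps one. Depth limits genes at low levels most: 1146 genes lay under the minimum level, and a wild-type count of 1 for *sodA* leaves its ratio between 3.64 and 870.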

Other observations

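The tests of runs of neighbouring tags were chosen after the data were seen.

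Besides the pyoverdine and iron-sulfur assembly tags, other neighbouring tags differed together by 2-fold or more on the rescaled values. In the *hfq* deletion, 9 measured tags from PP_3796 to PP_3804, the first of which is on the pyoverdine list, were at least 2-fold lower with a median log2 ratio of -2.10, and in the double deletion the median of the same run was -2.84. The run PP_0552 to PP_0557 was higher in the *hfq* deletion (6 tags, median 4.68), and extended by 1 tag to PP_0551 in the double deletion (7 tags, median 5.50). It did not appear in the *crc* deletion, where PP_0553 had 13 reads against 9 in the wild type. PP_4607 to PP_4612 were higher in the *hfq* deletion (6 tags, median 1.81), and PP_4607 to PP_4613 in the double deletion (7 tags, median 2.19). Not every run recurred: PP_1552 to PP_1569 were higher in the *hfq* deletion (10 measured tags, median 1.705), without such a run in the double deletion. Set against the *hfq* deletion, the double deletion was lower at PP_1555 to PP_1568 (8 measured tags, median -1.51). PP_0998 to PP_1003 were lower in the *crc* deletion (6 tags, median -1.73) and in the double deletion (median -2.62).

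Some runs stood apart in the double deletion. PP_3781 to PP_3789 (9 measured tags) had a median of -2.54 against the wild type and -2.31 against the *crc* deletion, and PP_3781 to PP_3786 had one of -2.22 against the *hfq* deletion. Runs of at least 6 neighbouring measured tags numbered 6 in the *hfq* deletion, 3 in the *crc* deletion and 10 in the double deletion, against at most 0, 1 and 1 in 1000 shuffles of the gene order. The counts include runs of pyoverdine tags and, with *hfq* deleted, the segment PP_3849 to PP_3920. Shuffling breaks up neighbours that vary together for any reason, so it cannot tell whether a deletion caused the runs. These runs were picked by their values, and what the genes encode was not analysed here.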
